A study of Homo sapiens with 32 samples.

How the data were processed

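Poly(A)-selected RNA of 32 glioblastoma specimens was measured by RNA sequencing. Per the labels' protocols, RNA was extracted with the Qiagen AllPrep DNA/RNA mini kit and libraries were made with the TruSeq RNA kit. The submitters' processing notes name BWA 0.5.7, GATK and the human genome build hg19, without the part each played. The counting method and the gene annotation are not given in the sources used here.

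The authors deposited 1 table of 20009 genes by 32 specimens, whose values were taken to be RPKM. The unit is not stated in the labels or the table and was inferred from the values. Values of low genes were whole multiples of a smallest step, and between specimens the steps of a gene kept nearly the same ratio as those of other genes. The step of a gene was its own smallest value, and genes were used if at least 2 specimens lay at 1 step. For 760 of these genes, whose step could be tied to a GENCODE transcript length, 99.9 percent of the 10739 values above 1.5 and below 200 steps lay within 0.05 step of a whole number, and for all such genes 77.7 percent of 36434 values. Values spread evenly would give 10 percent. For 495 of 496 specimen pairs the depth ratio was fitted within 0.1 percent. From this the depth was estimated as 84.3 to 138 M reads per specimen. Read counts as such were not used, so tests for counts were not run. RPKM depends on the reads in all genes of a library, so a large share on a few genes lowers the values of the rest. Reads from near-identical genes, and from overlapping genes on both strands, cannot be told apart with certainty. A protein-coding gene at 0 RPKM was read only as below the detection limit of that library.

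Genes on the Y chromosome and XIST (50 in all) were left out of every table. Of the other 19959 genes, 493 were at 0 in all specimens, and 13776 had at least 1 RPKM in at least 8 specimens and entered the tests. Values were analysed as log2(RPKM + 1), so changes of low genes are understated. The labels give 1 group (n = 32), which is the group used throughout. No batch is labelled. The specimens were compared over all genes before use, and 0 pairs of columns were identical. The reference annotation available was of another genome build, so it was used only for gene names and for which chromosome a gene lies on, and no coordinates are given.

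Before the data were examined, 38 gene lists were fixed (438 genes, 433 of them found in the table): 31 of cell types, pathways and programmes, and 7 of loci often amplified or deleted with their neighbours. A list score is the mean log2 value of the members that passed the filter. For each list with at least 4 such members, the median SD and the mean pairwise r were set against 10000 random lists of the same size matched on mean expression, and a score was read only above the 95th percentile of co-variation. For 35 score pairs, Pearson's r and Spearman's rho were computed with 2-sided p-values from 100000 permutations, adjusted by Benjamini-Hochberg over the 35, and r was computed again without the 2 specimens farthest from the median. Where the largest gap between neighbouring values exceeded 25 percent of the range with at least 3 specimens on either side, no pooled r was read. Neighbours of locus genes (27 pairs) were treated in the same way, with r within clusters of at least 6 specimens where the values split.

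Genes related to the pan-myeloid, proliferation and hypoxia scores and to EGFR were found with limma 3.58.1 in R 4.3.3, each term continuous, with trended empirical Bayes. A gene passed with a Benjamini-Hochberg adjusted p below 0.05 and an absolute r of at least 0.5, and members of the list that gave the score were left out. Lists were tested against each term with camera, with its preset and again with an estimated correlation, and with fry, which tests a list on its own and not against other genes. Counts of list members were also adjusted over the list alone. Genes named in the text are, for each term, the 10 with the highest and the 10 with the lowest r among those that passed, members of the fixed lists with the highest and lowest level or r, the 20 genes with the largest SD, and all genes of the score pairs and loci. Genes singled out beyond this rule were chosen after their values were seen, and a few genes that the rule takes are not reported here. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

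The methods were tested on simulated data. In a simulation of the pan-myeloid comparison with 13776 genes, limma recovered 100 percent of genes made with an r of 0.8 or -0.8 and 62 percent of those made with 0.6 or -0.6, with 9 false calls. Apart from that r the simulated genes varied independently, whereas real genes vary together. The 9 false calls therefore do not measure the error rate in these data. Random orders of the real terms, given below, called up to 12 genes for pan-myeloid, 383 for proliferation, 1612 for hypoxia and 1065 for EGFR. The random list method passed 100 percent of 30 related and 6.2 percent of 500 unrelated simulated lists for co-variation, and 100 percent of 30 and 3 percent of 500 for spread. The permutation test of r passed 4.6 percent of 500 unrelated pairs and 95.4 percent of pairs with an r of 0.6. The swap test of a difference in r passed 6.2 percent of 500 equal pairs and 98.8 percent of unequal ones. The share of the median slope on EGFR kept with the neuron and oligodendrocyte scores as covariates was -0.0123 for 3000 simulated genes that followed only these scores and 0.997 for genes that followed EGFR itself. Among those with an absolute r of at least 0.5 it was 0.666 and 1.0.

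Settings tried as planned were a pseudocount of 0.1, no filter, a filter of at least 5 RPKM in at least 16 specimens, upper-quartile scaling, quantile normalization, Spearman ranks, mean z-scores, leaving out the 2 farthest specimens, and the neuron and oligodendrocyte scores or the number of genes at 1 RPKM as covariates. Chosen after seeing the data were the mitochondrial share (the percent of summed RPKM on mitochondrial-encoded genes) as a covariate, leaving out the 2 most alike specimens, leaving out the 6 specimens above a 20 percent mitochondrial share, and, for the locus neighbours, partial correlations and leaving out the 1 farthest specimen. The swap test of the macrophage against the microglia score was also chosen then.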

Results

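Messenger RNA was profiled in 32 specimens of glioblastoma, a grade IV tumour of the brain, by sequencing poly(A)-selected RNA on an Illumina HiSeq instrument. The labels place all 32 specimens in 1 group and name no treatment, normal tissue or batch, so no comparison between groups was made. They do not say whether the specimens came from different patients, so p-values treat them as independent and measure only the spread between these samples. Levels are given in RPKM (reads scaled to transcript length and to the size of the library), and correlations and scores were computed on log2(RPKM + 1). The depth, estimated from the step size of low values, was 84.3 to 138 M reads per specimen (median 105 M). Between 11427 and 13153 genes reached 1 RPKM in a specimen, and 13776 genes reached it in at least 8 specimens.

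Astroglial transcripts were among the most abundant of the genes in the fixed lists. GFAP, the intermediate filament of astrocytes, had a median of 2892 RPKM (quartiles 1794 to 4356), CLU 1294 RPKM, MT3 992 RPKM and VIM 949 RPKM. The neural stem cell factor SOX2 was at 106 RPKM, OLIG2 at 42.4 RPKM and the intermediate filament gene NES at 84.7 RPKM. NANOG was at 0 RPKM in the median specimen and reached 1 RPKM in 0 of 32, and POU5F1 reached it in 3 of 32. The catalytic telomerase gene TERT reached 1 RPKM in 0 of 32 specimens (median 0.078 RPKM). MGMT, which repairs alkylated guanine, had a median of 4.31 RPKM (range 0.616 to 12.3).

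The 20 genes with the largest spread were mostly myelin, neuronal, matrix and mesenchymal genes. The myelin gene MBP had an SD of 3.59 log2 units and ranged from 3.63 to 20172 RPKM, and MAG, MOBP, MOG, ERMN, KLK6, CNDP1 and NKX6-2, most of them also oligodendrocyte genes, had SDs of 2.36 to 2.77. The secreted glycoprotein gene CHI3L1 had an SD of 3.31 (0.613 to 6633 RPKM), POSTN 3.11 and the collagen gene COL3A1 2.56, with COL1A1 next to it. EGFR had an SD of 2.91, LTF 2.57, IGFBP2 2.47, the chemokine gene IL8 2.36, and the neuronal genes VSNL1, SLC17A7 and STMN2 2.42, 2.41 and 2.37. The median SD of all genes that passed the filter was 0.53, and their 95th percentile was 1.27.

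Pan-myeloid genes were abundant, whereas most lymphocyte genes were near the lower limit. The complement genes C1QB and C1QA had medians of 169 and 117 RPKM, the adaptor gene TYROBP 90.5 RPKM (range 35.3 to 391), and the class II invariant chain CD74 483 RPKM. The microglial genes P2RY12 and TMEM119 had medians of 16.5 and 10.2 RPKM. The scavenger receptor CD163, a macrophage gene, ranged from 0.565 to 331 RPKM (median 12.5). Among T cell genes, CD3D, CD3E, CD2 and CD8A had medians of 0.231, 0.362, 0.358 and 0.399 RPKM and reached 1 RPKM in 6, 7, 8 and 8 specimens. FOXP3, the regulatory T cell factor, reached 1 RPKM in 0 of 32 specimens (median 0.245 RPKM), and the B cell gene MS4A1 also in 0 of 32. Only 2 of 14 T cell genes, 3 of 7 regulatory T cell genes and 0 of 9 B and plasma cell genes passed the filter, so the scores of these lists were not read. The same held for the red blood cell list, with 3 of 8 genes passing (HBA1, HBA2 and HBB), and the replication-dependent histone list, with 1 of 10 (HIST1H1C, median 15.2 RPKM).

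Among immune checkpoint genes, 8 of 16 passed the filter, and the T cell receptors PDCD1, LAG3, TIGIT and CTLA4 were below 1 RPKM in all or all but 1 of the specimens. CD276 had a median of 21 RPKM (2.91 to 105), C10orf54, the gene of the checkpoint VISTA, 13.3 RPKM, LGALS9 13 RPKM, HAVCR2 7.90 RPKM, CD86 5.77 RPKM and ICOSLG 3.30 RPKM. The PD-1 ligand genes PDCD1LG2 and CD274 had medians of 1.57 and 0.935 RPKM and reached 1 RPKM in 20 and 16 specimens. PDCD1, LAG3, TIGIT, CD80 and VTCN1 reached 1 RPKM in 0 of 32 specimens, CTLA4 in 1, IDO1 in 5 and TNFSF4 in 6.

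**Figure D1:**
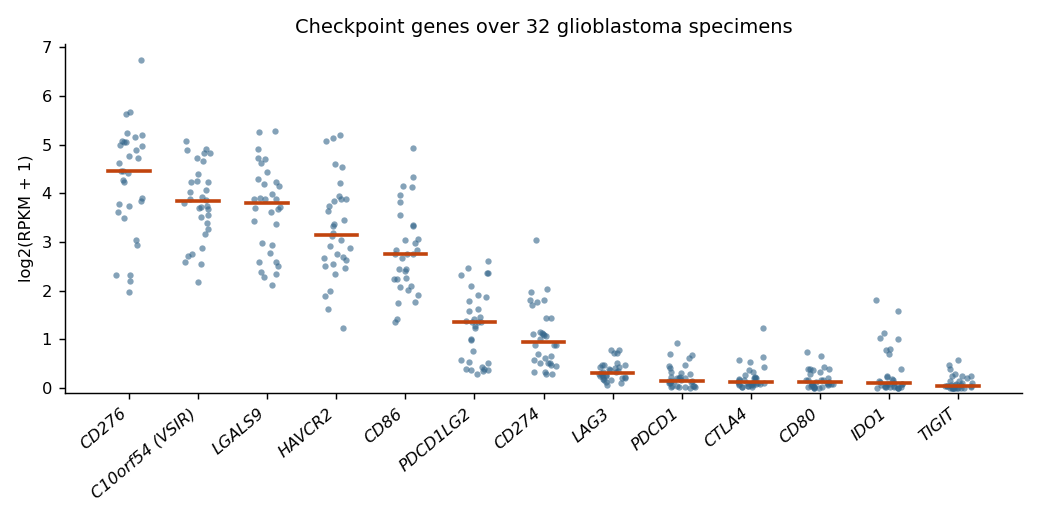
Levels of 13 checkpoint genes over the 32 glioblastoma specimens, as log2(RPKM + 1) on the vertical axis, with 1 point per specimen and a bar at the median. CD276 (median 21 RPKM) is the highest of the 13 medians and TIGIT (median 0.0378 RPKM) the lowest.

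Most cell type and programme lists varied more than genes of like level, and their members varied together. Of 26 lists with at least 4 genes past the filter, 24 had a median SD above the 95th percentile of 10000 random lists matched on size and mean expression. The 2 others were the cytotoxic lymphocyte list (92.6th percentile) and the ribosomal protein list (9.78th percentile, median SD 0.57). The median SD was 2.39 for the oligodendrocyte list, 2.07 for the neuron list, 1.66 for the oligodendrocyte-progenitor-like list, 1.64 for the mesenchymal-like list and 1.59 for the monocyte-derived macrophage list. The mean pairwise r of members was 0.94 in the mitochondrial-encoded list, 0.92 in the proliferation list, 0.88 in the oligodendrocyte list and 0.86 in both the pan-myeloid and the neuron list. It lay within the random range in the receptor tyrosine kinase and ligand list (0.077, 49.3rd percentile) and in the list of cell cycle genes (0.17, 89.9th percentile), so these 2 lists were read gene by gene.

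HLA class II, checkpoint and myeloid suppressive and chemotactic genes rose as lists with the pan-myeloid score, and leukocyte genes were among those with the highest r. By limma, 1585 genes were higher and 516 lower with a higher score (adjusted p below 0.05 and an absolute r of at least 0.5) among 13761 tested. The genes with the highest r were ADAP2 (r = 0.97), SASH3, CD53, ITGB2, FERMT3, SIGLEC9, NCKAP1L, LRRC25, CTSS and CD86. ITGB2, the beta chain of the leukocyte integrins, gained 1.01 ± 0.056 (SE, n = 32) log2 units per unit of score (limma adjusted p = 3.06e-15), and CD86, a costimulatory ligand, 0.84 ± 0.054 (adjusted p = 4.21e-14). The genes with the lowest r were TRIM7 (r = -0.80), MESP1, ZNF540, SLC25A23, OLFM1, KIF3A, the synaptic vesicle gene SYP (r = -0.71), YPEL1, BEX1 and TIGD3. After quantile normalization the split of the calls was 1219 higher and 743 lower. The number of lower genes was 214 without the 2 farthest specimens, 182 with the neuron and oligodendrocyte scores as covariates, and 1114 without the 6 specimens above a 20 percent mitochondrial share. The median slope of the 2101 calls, each in the direction of its call, was 0.45 (median SE 0.090), and 0.41 (0.10), 0.38 (0.097) and 0.41 (0.095) in these settings, with the sign of all 2101 unchanged in each.

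Of the lists tested against the pan-myeloid score, all 10 HLA class II genes, all 8 checkpoint genes that passed the filter (of 16 listed) and 8 of 15 myeloid suppressive and chemotactic genes rose with it. Their camera adjusted p-values were 7.95e-16, 3.24e-09 and 7.83e-06, and these 3 of 17 calls held with an estimated correlation (adjusted p = 0.0071, 2.76e-05 and 0.0303). HLA-DMA had an r of 0.95 and HLA-DQB1 of 0.52, HAVCR2 of 0.92, CD274 of 0.61, the fibrinogen-like gene FGL2 of 0.89 and SPP1 of 0.76. Genes of the HLA family share sequence, so reads of close members cannot be told apart with certainty. Whether myeloid cells themselves expressed the genes of these 3 lists was not tested. Their rise can therefore not be told apart from a larger amount of myeloid RNA. Among the other lists, 9 of 10 macrophage genes (STAB1 0.86; not VCAN, 0.14), 5 of 10 microglia genes (BIN2 0.85; P2RY12 0.16 and SALL1 -0.01 did not pass) and 16 of 18 mesenchymal-like genes (S100A11 0.90) rose. So did 11 of 12 HLA class I genes, 4 of 8 neutrophil genes and 4 of 6 cytotoxic lymphocyte genes. With an estimated correlation their adjusted p-values were 0.0765 for the macrophage, HLA class I, neutrophil and cytotoxic lists, 0.123 for microglia and 0.169 for the mesenchymal-like list. Of the neuron list, 3 of 11 genes fell, among them SNAP25 and STMN2 (-0.59 and -0.53; adjusted p = 0.206 with an estimated correlation). The oligodendrocyte-progenitor-like, neural-progenitor-like, astrocyte-like and mitochondrial-encoded lists were also lower by camera (adjusted p = 7.61e-05, 1.4e-05, 0.00861 and 0.00968) and the immediate early list higher (0.000552), with adjusted p-values of 0.206, 0.206, 0.426, 0.558 and 0.371 with an estimated correlation. In every list and for each of the 4 terms, the counts adjusted over the list alone equalled those adjusted over all genes.

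Macrophage and microglia genes were related differently to the mesenchymal-like and hypoxia lists. The monocyte-derived macrophage score rose with the mesenchymal-like score (r = 0.84, p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 0.000117, rho = 0.88, adjusted p = 0.000117; r = 0.85 without the 2 specimens farthest from the median). The microglia score had an r of 0.066 with it (p = 0.72, rho = 0.048) and an r of 0.089 with the macrophage score (p = 0.63, rho = 0.15). With the hypoxia score the macrophage r was 0.54 (adjusted p = 0.00497, rho = 0.61). It no longer passed given the mitochondrial share (0.23, adjusted p = 0.266), given the neuron and oligodendrocyte scores (0.37, adjusted p = 0.0657) or without the 6 specimens above a 20 percent mitochondrial share (0.25, adjusted p = 0.276). The microglia r with hypoxia was -0.41 (adjusted p = 0.0389, rho = -0.38, adjusted p = 0.0577; -0.32 without the 2 farthest specimens, p = 0.087). It rested in part on these 2, but was -0.56 without the 2 most alike specimens and -0.43 given the mitochondrial share and the neuron and oligodendrocyte scores. A permutation that swapped the 2 scores within specimens, chosen after these values were seen, gave a difference in r of 0.77 for the mesenchymal-like score (p = 3e-05) and 0.95 for hypoxia (p = 1e-05). The macrophage score fell with the mitochondrial share of a library (r = -0.64, adjusted p = 0.000427, rho = -0.64), as did the mesenchymal-like score (r = -0.73, adjusted p = 4.5e-05, rho = -0.62). The microglia score had an r of 0.065 with that share (p = 0.731, rho = 0.27, p = 0.14), and of 0.41 without the 2 farthest specimens.

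**Figure D2:**
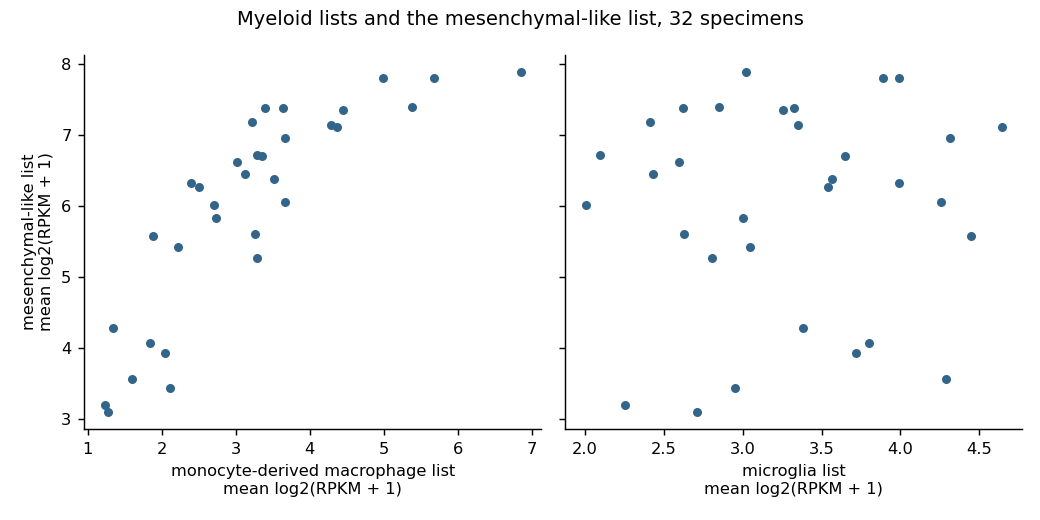
Mean log2(RPKM + 1) of the mesenchymal-like list (vertical axes) against that of the monocyte-derived macrophage list (left) and the microglia list (right), with 1 point per specimen (n = 32). Points rise together on the left (r = 0.84) and show no trend on the right (r = 0.066).

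Of 35 score pairs set in advance, 5 used the unread T cell score. Among the other 30, 11 rose together and 6 ran against each other at an adjusted p below 0.05. The pan-myeloid score rose with the HLA class II score (r = 0.92, adjusted p = 0.000117, rho = 0.86) and with the mesenchymal-like score (r = 0.67, adjusted p = 0.000175, rho = 0.67). VEGFA and ADM, both induced by low oxygen, had an r of 0.93 (adjusted p = 0.000117, rho = 0.89), and the mesenchymal-like and hypoxia scores one of 0.67 (adjusted p = 0.00014, rho = 0.65). The endothelial score rose with the pericyte and fibroblast score (r = 0.64, adjusted p = 0.0003, rho = 0.64) but had an r of 0.057 with hypoxia (adjusted p = 0.756). The interferon response score rose with HLA class I (r = 0.49, adjusted p = 0.0124, rho = 0.64), the neuron with the oligodendrocyte score (r = 0.44, adjusted p = 0.0285, rho = 0.42), and PDGFRA with the oligodendrocyte-progenitor-like score (r = 0.42, adjusted p = 0.0374, rho = 0.51). PDGFRA, a member of that list, was left out of its score for this pair. The mesenchymal-like and proliferation scores had an r of 0.62 (adjusted p = 0.000962), while rho was 0.38 (adjusted p = 0.0577). Given the mitochondrial share, the following no longer passed: the mesenchymal-like score had an r of 0.40 with hypoxia (adjusted p = 0.0554) and 0.14 with proliferation (adjusted p = 0.448), and the neuron with the oligodendrocyte score 0.16 (adjusted p = 0.415). Nor did PDGFRA with a pseudocount of 0.1 (0.37, adjusted p = 0.0551) or given the neuron and oligodendrocyte scores (0.39, adjusted p = 0.0562), or interferon with HLA class I given the number of genes at 1 RPKM (0.34, adjusted p = 0.0865) or without the 2 most alike specimens (0.39, adjusted p = 0.0591). Without the 2 farthest specimens the r of the 11 pairs was 0.40 to 0.93, the lowest being the neuron with oligodendrocyte pair (adjusted p = 0.0601). Over all 17 pairs the unadjusted p of r was 1e-05 to 0.0236. The adjusted p of rho was 0.0346 or lower (unadjusted 0.0188 or lower), apart from the mesenchymal-like with proliferation, the microglia with hypoxia and the pan-myeloid with oligodendrocyte-progenitor-like pairs.

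Scores that ran against each other were mostly those of myeloid or mesenchymal-like genes against neural genes. The mesenchymal-like and neural-progenitor-like scores had an r of -0.45 (adjusted p = 0.0219, rho = -0.54; -0.55 without the 2 farthest specimens), and the immediate early and neuron scores one of -0.40 (adjusted p = 0.0413, rho = -0.42; -0.42 without the 2 farthest). The pan-myeloid score had an r of -0.46 with both the oligodendrocyte-progenitor-like and the neural-progenitor-like score (adjusted p = 0.0201 for each, rho = -0.36 with an adjusted p = 0.072 and rho = -0.42) and of -0.50 with the neuron score (adjusted p = 0.0115, rho = -0.44). Each of these 3 relations rested in part on 2 specimens, without which r was -0.22, -0.29 and -0.33. For the 2 progenitor-like pairs these were the 2 specimens with the highest pan-myeloid scores. For the neuron pair they were the 2 most alike specimens, which had the highest neuron scores. Given the mitochondrial share, the neuron score had an r of -0.35 with the immediate early and -0.33 with the pan-myeloid score (adjusted p = 0.0959 and 0.11). The immediate early with neuron relation also no longer passed after upper-quartile scaling (-0.34, adjusted p = 0.0945), after quantile normalization (-0.35, adjusted p = 0.0816), given the oligodendrocyte score (-0.38, adjusted p = 0.0606) or without the 2 most alike specimens (-0.29, adjusted p = 0.171). Given the neuron and oligodendrocyte scores, the neural-progenitor-like score had one of -0.30 with the mesenchymal-like and -0.34 with the pan-myeloid score (adjusted p = 0.14 and 0.0953). Of the pairs that did not pass, EGFR with PDGFRA had an r of -0.21 (adjusted p = 0.299), EGFR with the astrocyte-like score 0.24 (adjusted p = 0.241; 0.45 given the neuron and oligodendrocyte scores, where it passed, adjusted p = 0.0255), the pan-myeloid with the proliferation score 0.13 (adjusted p = 0.546) and neutrophil with hypoxia 0.096 (adjusted p = 0.656). The interferon score had an r of 0.30 with CD274 (adjusted p = 0.142), while rho was 0.54 (adjusted p = 0.00585). The neuron with proliferation r was -0.38 (adjusted p = 0.0553) and passed after upper-quartile scaling (-0.42, adjusted p = 0.0341), with a rho of -0.18.

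Mitochondrial-encoded genes fell with the proliferation score, as a list with a camera adjusted p = 0.113 with an estimated correlation. The genes with the highest r were mostly mitotic, but no list of mitotic genes apart from the one that gave the score was tested. By limma, 3636 genes were higher and 469 lower with a higher proliferation score among 13758 tested. The highest r belonged to KIF20A (r = 0.99), NUSAP1, NDC80, FOXM1, HJURP, KIFC1, CKAP2L, CDCA8, CENPA and NCAPH, most of them genes of mitosis. FOXM1, a transcription factor of the late cell cycle, gained 1.13 ± 0.040 (SE, n = 32) log2 units per unit of score (limma adjusted p = 2.83e-21). The lowest r belonged to MT-ND4 (r = -0.83), AC090186.1, MT-ND3, MT-ND4L, LDHD, MT-ND2, ACY3, CBX7, FRA10AC1 and NRN1L. All 12 mitochondrial-encoded genes fell (camera adjusted p = 1.13e-19; adjusted p = 0.113 with an estimated correlation), and the mitochondrial share of the library fell with the score (r = -0.76, adjusted p = 0.00014, rho = -0.71). Among the list of cell cycle genes, 7 of 16 rose, including CDK6 (0.73) and CDKN1A (0.64). The list as a whole did not pass camera (adjusted p = 0.369).

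Of the mesenchymal-like list, 12 of 18 genes rose with proliferation (TAGLN2 0.80; EFEMP1, at 0.14, did not pass; camera adjusted p = 0.000806; adjusted p = 0.881 with an estimated correlation). So did 8 of 15 hypoxia genes (VEGFA 0.75; camera adjusted p = 0.134), and the checkpoint gene CD276 (0.70). Of the microglia list, 4 of 10 genes fell (P2RY13 -0.60, P2RY12 -0.59, CX3CR1 -0.55 and TAL1 -0.55; camera adjusted p = 0.000749; adjusted p = 0.758 with an estimated correlation). The oligodendrocyte list (mean r -0.37, 1 of 12 genes passing, OPALIN at -0.53) and the neuron list (mean r -0.36, 0 of 11) had camera adjusted p-values of 8.7e-06 and 2.45e-05 in the same direction, and the same adjusted p = 0.758 with an estimated correlation. The ribosomal protein and astrocyte-like lists were also lower by camera (adjusted p = 0.041 and 0.0423; adjusted p = 0.881 with an estimated correlation). The split of the calls was 1873 higher and 1138 lower after upper-quartile scaling, and 1672 and 1263 after quantile normalization. With the mitochondrial share as a covariate, chosen after seeing the data, 521 genes were higher and 65 lower, and without the 6 specimens above a 20 percent share 692 and 108. With that covariate 511 of the 4105 calls still passed, and the median slope of the 4105, each in the direction of its call, went from 0.27 (median SE 0.057) to 0.14 (median SE 0.081).

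Most proliferation and mesenchymal-like genes rose with the hypoxia score, and mitochondrial-encoded genes fell. As lists, these passed camera with its preset but not with an estimated correlation (adjusted p = 0.431, 0.431 and 0.347), and 40 of the 2206 calls below still passed with the mitochondrial share of the library as a covariate. By limma, 1794 genes were higher and 412 lower with a higher score among 13761 tested. The highest r belonged to INSIG2 (r = 0.91), C7orf68, RP11-196G11.1, VKORC1, QPCTL, GBE1, GAPDH, AKAP12, ANGPTL4 and IGFBP5. C7orf68, the lipid droplet gene also called HILPDA, gained 1.96 ± 0.181 (SE, n = 32) log2 units per unit of score (limma adjusted p = 2.26e-08), and the glycolytic gene GAPDH 0.84 ± 0.117 (adjusted p = 2.23e-05). The lowest r belonged to ACY3 (r = -0.81), RP11-162P23.2, NET1, DHRS9, the aldehyde dehydrogenase ALDH2 (r = -0.75), C3orf54, CLEC9A, CA4, RXRG and PTH1R.

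Of the proliferation list, 16 of 18 genes rose with the hypoxia score (UBE2C 0.73; MCM5, at 0.46, did not pass) and of the mesenchymal-like list 15 of 18 (TAGLN2 0.72; S100A11, at 0.38, did not pass). Their camera adjusted p-values were 1.41e-10 and 2.57e-09, and for both the adjusted p = 0.431 with an estimated correlation. All 12 mitochondrial-encoded genes fell (MT-CYB -0.68, MT-ND6 -0.55; adjusted p = 0.347 with an estimated correlation), and the mitochondrial share fell with the score (r = -0.63, adjusted p = 0.000336, rho = -0.64). Lower with the score by camera were also the oligodendrocyte list (mean r -0.38, 1 of 12 genes passing, OPALIN at -0.53; adjusted p = 1.15e-06), the neuron list (mean r -0.37, 0 of 11; adjusted p = 4.49e-06) and the microglia list (4 of 10 passing, among them P2RY13 at -0.59; adjusted p = 0.000217). Each had an adjusted p = 0.431 with an estimated correlation. The interferon response, astrocyte-like and oligodendrocyte-progenitor-like lists were lower too (adjusted p = 0.00754, 0.0439 and 0.0439), and the macrophage, HLA class I, myeloid suppressive and pericyte lists higher (0.00741, 0.0151, 0.0284 and 0.0439), none of them with an estimated correlation (adjusted p = 0.675 or 0.737). The split of the calls was 747 higher and 441 lower after upper-quartile scaling, and 721 and 429 after quantile normalization. Of the 2206 calls, 40 still passed with the mitochondrial share as a covariate (36 higher and 9 lower genes in all), 32 without the 6 specimens above a 20 percent share (28 and 4) and 472 with the neuron and oligodendrocyte scores as covariates (406 and 84). The median slope of the calls was 0.50 (median SE 0.13), and 0.23 (0.14), 0.30 (0.15) and 0.35 (0.13) in these settings.

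EGFR, the receptor gene most often amplified in glioblastoma, ranged from 0.0655 to 1047 RPKM (median 18.8) and exceeded 4 times its median in 7 of 32 specimens. By limma, 1322 genes were higher and 180 lower with higher EGFR among 13775 tested. The highest r belonged to C1orf226 (r = 0.78), RSRC1, RP11-565P22.6, the metalloprotease inhibitor gene TIMP3 (r = 0.75), STAG3L2, STAG3L1, the kinase gene PRKD1 (r = 0.74), STAG3L3, KRIT1 and ZNF486. TIMP3 gained 0.21 ± 0.033 (SE, n = 32) log2 units per log2 unit of EGFR (limma adjusted p = 0.00161). STAG3L1, STAG3L2 and STAG3L3 are near-identical copies whose reads cannot be told apart with certainty. The lowest r belonged to POPDC3 (r = -0.72), SVIP, NDUFB8, PIGP, FHIT, ATP5I, ETFB, PFDN2, SEPT1 and RP1-177G6.2, of which NDUFB8 (-0.66), ATP5I (-0.66) and ETFB (-0.66) are nuclear genes of mitochondrial respiration.

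Of the stem cell and glioma transcription factors, 4 of 10 rose with EGFR (POU3F2 0.70, ZEB1 0.62, NES 0.61 and BMI1 0.51; camera adjusted p = 0.0158; adjusted p = 0.931 with an estimated correlation). Of the HLA class I list, 3 of 12 rose (TAP1 0.58, TAP2 0.55 and NLRC5 0.53; the same adjusted p = 0.931). Of the mitochondrial-encoded list, 5 of 12 fell (MT-CO3 -0.52; adjusted p = 0.454 with an estimated correlation), and the mitochondrial share had an r of -0.50 with EGFR (adjusted p = 0.00997, rho = -0.47). The oligodendrocyte list (mean r -0.43, 1 of 12 genes passing, OPALIN at -0.51) and the neuron list (mean r -0.35, 0 of 11) were lower with EGFR by camera (adjusted p = 1.93e-10 and 2.61e-07), and had an adjusted p = 0.454 and 0.593 with an estimated correlation. Also lower were the ribosomal protein, neutrophil, microglia and immediate early lists (adjusted p = 0.00198, 0.0158, 0.0225 and 0.0395), and higher the proliferation list (0.00445, 0 of 18 genes passing), all with an adjusted p = 0.931 with an estimated correlation. The split of the calls was 745 higher and 339 lower after upper-quartile scaling, and 554 and 336 after quantile normalization. Fewer genes passed without the 2 specimens with EGFR farthest from the median (157 higher and 17 lower), without the 2 most alike specimens (41 and 7) and with the neuron and oligodendrocyte scores as covariates (14 and 0). At an unadjusted p below 0.05 limma gave 3997 higher and 919 lower over all specimens, and 3285 and 656, 2108 and 552, and 1890 and 327 in these 3 settings. With the mitochondrial share as a covariate, or without the 6 specimens above a 20 percent share, limma called 0 genes, against 1121 higher and 422 lower, or 693 and 290, at an unadjusted p below 0.05. The median slope of the 1502 calls, each in the direction of its call, was 0.106 (median SE 0.0288) over all specimens and also 0.106 (0.0338) without the 2 farthest. It was 0.084 (0.029) without the 2 most alike, 0.0747 (0.0309) with the neuron and oligodendrocyte scores, 0.0633 (0.0289) with the mitochondrial share and 0.0607 (0.0306) without the 6.

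Of the genes beside loci that are often amplified or deleted in glioblastoma, 8 of 13 tested over all 32 specimens passed with the locus gene. Some of these relations rested on 1 or 2 specimens. For loci other than EGFR, genes away from the locus were not compared. Whether those relations are particular to neighbours was therefore not tested. With EGFR, 1322 of the 13775 genes tested above rose with an r of at least 0.5. Among them C1orf226 (r = 0.78), RSRC1 (0.77) and TIMP3 (0.75), which are not among its listed neighbours, exceeded every listed neighbour. An r of this size with EGFR was therefore not particular to the listed neighbours. Over all 32 specimens EGFR rose with VOPP1 (r = 0.68, adjusted p = 3.86e-05, rho = 0.67), SEC61G (r = 0.55, adjusted p = 0.00228, rho = 0.56) and LANCL2 (r = 0.51, adjusted p = 0.00385, rho = 0.42), and VSTM2A had an r of 0.092. Without the 2 specimens farthest from the median, these 3 were 0.57, 0.51 and 0.35, the last no longer passing (p = 0.0561). PDGFRA, above 4 times its median in 8 specimens (maximum 933 RPKM), rose with FIP1L1 (r = 0.95, adjusted p = 3.86e-05, rho = 0.89) but had an r of 0.23 with KIT and -0.014 with KDR. CDKN2A (0.212 to 95.6 RPKM) rose with CDKN2B (r = 0.86, adjusted p = 3.86e-05, rho = 0.82) and MTAP (r = 0.58, adjusted p = 0.00102, rho = 0.63). Without the 2 farthest, r was 0.91 for FIP1L1, 0.89 for CDKN2B and 0.55 for MTAP. In all, 8 of 13 such pairs passed, with an unadjusted p of 1e-05 to 0.029 for r and, MDM4 apart, an adjusted p of 0.000135 to 0.0282 for rho. Of these, MDM4 with PIK3C2B and with LRRN2 (r = 0.53 and 0.59, rho = -0.15 and 0.27 with an adjusted p = 0.52 and 0.192) rested on 1 specimen, without which r was -0.29 and 0.17 (p = 0.114 and 0.371). MET, with a median of 0.752 RPKM, had an r of -0.068 with CAPZA2 and -0.054 with ST7.

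CDK4 and MDM2 each fell into a cluster of 29 specimens and one of 3 high ones (maxima 2147 and 765 RPKM), and no pooled r was read. The 3 high specimens were the same for both genes. Within the 29 lower specimens CDK4 rose with 7 of 8 neighbours by Pearson's r, most strongly with TSFM (r = 0.81, adjusted p = 3.5e-05, rho = 0.59), OS9 (r = 0.77, rho = 0.55), METTL1 (r = 0.73, rho = 0.55), TSPAN31 (r = 0.70, rho = 0.56) and CYP27B1 (r = 0.69, rho = 0.46). MARCH9 (r = 0.51, rho = 0.45) and AVIL (r = 0.44, adjusted p = 0.0221, rho = 0.24, adjusted p = 0.252) were weaker, and AGAP2 had an r of -0.18 (adjusted p = 0.345). MDM2 rose there with NUP107 (r = 0.73, rho = 0.61), RAP1B (r = 0.69, rho = 0.63) and CPM (r = 0.51, rho = 0.43), and SLC35E3 fell (r = -0.46, adjusted p = 0.0158, rho = -0.48). The pooled r of SLC35E3, not read because of the clusters, had the other sign (0.75, rho = -0.10). CYP27B1 and SLC35E3 lay near the lower limit, with medians of 0.309 and 0.238 RPKM. CHIC2, within 28 specimens, had an r of 0.19 with PDGFRA, and WNT2, within 29, one of 0.37 with MET (adjusted p = 0.345 and 0.0548). Over the 11 neighbours of CDK4 and MDM2 that passed, the unadjusted p of r was 1e-05 to 0.0174 and, AVIL apart, the adjusted p of rho 0.00413 to 0.0276. Without the 2 farthest of the 29, AVIL and CPM no longer passed (r = 0.28 and 0.38, adjusted p = 0.182 and 0.071), and r was -0.52 for SLC35E3 and 0.54 to 0.79 for the others. The 3 or 4 specimens of each high cluster were too few for a test. The r within the lower clusters was computed without covariates. The specimens with the lowest CDK4 (9.12, 10.2, 11.9 and 17.8 RPKM) had high mitochondrial shares (37.0, 44.4, 21.6 and 33.3 percent). A relation through that share was therefore not tested within the 29.

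**Figure D3:**
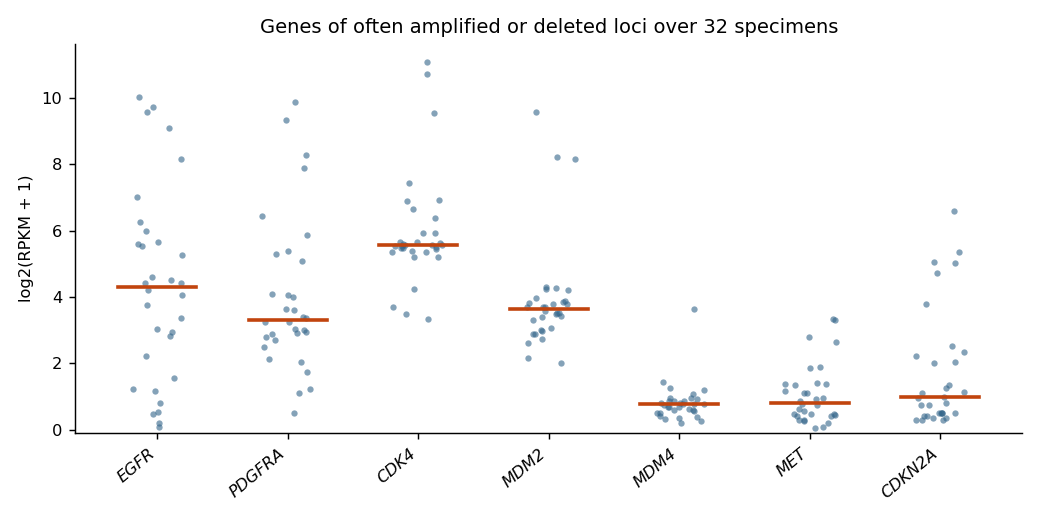
Levels of 7 genes of often amplified or deleted loci over the 32 specimens, as log2(RPKM + 1) on the vertical axis, with 1 point per specimen and a bar at the median. CDK4 and MDM2 have the same 3 specimens set apart from the other 29, while EGFR spreads without such a gap from 0.0655 to 1047 RPKM.

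The share of mitochondrial-encoded transcripts ranged from 3.15 to 44.4 percent of the summed RPKM (median 9.56 percent). It had an r of 0.88 with principal component 1 (adjusted p = 0.00014, rho = 0.80), which held 29.7 percent of the variance and ran from neuronal and myelin genes such as SNAP25 and MBP to POSTN, COL3A1 and CHI3L1. The share rose with the neuron score (r = 0.73, adjusted p = 6e-05, rho = 0.55; 0.56 without the 2 farthest specimens) and the oligodendrocyte score (r = 0.47, adjusted p = 0.0107, rho = 0.44). Component 2, with 13.9 percent, ran from TNR, BCAN and OLIG2 to S100A8, S100A9 and IL8. For all relations of the mitochondrial share given here as passing, the unadjusted p of r was 1e-05 to 0.00592 and the adjusted p of rho 0.00018 to 0.0288. Without the 2 farthest specimens r was -0.70 for proliferation, -0.61 for hypoxia and for the mesenchymal-like score, -0.58 for the macrophage score, -0.39 for EGFR, 0.47 for the oligodendrocyte score and 0.81 for component 1. The ribosomal protein share ranged from 1.21 to 4.42 percent and the red blood cell share from 0.00678 to 4.17 percent. The 2 most alike specimens had an r of 0.971 over genes, against 0.950 for the next pair and a median of 0.862 over the 496 pairs. The SD of their log2 difference was 0.45 over all genes tested, against a median of 0.92 over pairs, and 0.50 over 2123 genes at 20 RPKM or more. These 2 specimens also had the 2 highest mitochondrial shares (37.0 and 44.4 percent) and the 2 highest neuron scores (6.79 and 6.12). Leaving them out therefore also removes the extremes of both measures and is not a separate check. The labels do not say whether the 2 came from 1 patient. They were counted as 2 samples.

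**Figure D4:**
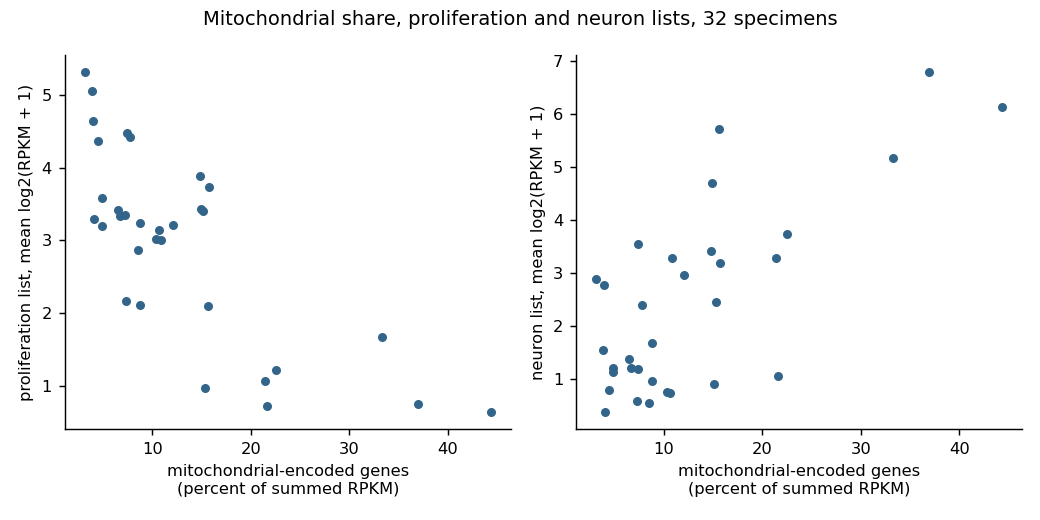
Mean log2(RPKM + 1) of the proliferation list (left) and the neuron list (right), on the vertical axes, against the percent of summed RPKM on mitochondrial-encoded genes, with 1 point per specimen (n = 32). The share spans 3.15 to 44.4 percent, and proliferation falls (r = -0.76) and the neuron list rises (r = 0.73) along it.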

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

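Tests with the mitochondrial share, without the 1 farthest specimen, without the 2 most alike specimens and without the 6 specimens above a 20 percent mitochondrial share were chosen after the results were seen; the other alternatives were planned. Unless a reason is given, the cause was not tested. Counts are given as higher and lower genes, where they moved by over 1.5 times, against 1585 and 516 for the pan-myeloid score, 3636 and 469 for proliferation, 1794 and 412 for hypoxia and 1322 and 180 for EGFR.

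The stricter filter, which tests fewer genes (8239), gave 895 and 316 for pan-myeloid, 2414 and 202 for proliferation, 175 lower for hypoxia, and 734 and 103 for EGFR. With no filter 741 genes were lower with proliferation. Upper-quartile scaling gave 1873 and 1138 for proliferation, 747 higher for hypoxia, and 745 and 339 for EGFR, and quantile normalization 1672 and 1263, 721 higher, and 554 and 336. Spearman ranks gave 311 lower for pan-myeloid and 277 lower for proliferation. Without the 2 specimens farthest from the median of the term, 214 genes were lower with pan-myeloid, 2289 higher with proliferation, and 157 and 17 higher and lower with EGFR.

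With the neuron and oligodendrocyte scores as covariates, 182 were lower with pan-myeloid, 2420 and 226 moved with proliferation, 406 and 84 with hypoxia, and 14 and 0 with EGFR (1890 and 327 at an unadjusted p below 0.05, limma). With the number of genes at 1 RPKM as a covariate, 980 were lower with pan-myeloid, 2354 higher with proliferation, and 40 and 9 moved with EGFR. The mitochondrial share as a covariate gave 521 and 65 for proliferation, 36 and 9 for hypoxia, and 0 and 0 for EGFR by limma (1121 and 422 at an unadjusted p below 0.05). Without the 2 most alike specimens 1068 were higher with hypoxia, and 41 and 7 moved with EGFR. Without the 6 specimens, which leaves fewer samples, 1114 were lower with pan-myeloid, 692 and 108 moved with proliferation, 28 and 4 with hypoxia, and 0 and 0 with EGFR by limma (693 and 290 at an unadjusted p below 0.05).

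Of the score pairs, 7 instead of 11 were positive given the mitochondrial share, and 7 without the 6 specimens. Of the 6 negative pairs, 3 passed given the neuron and oligodendrocyte scores, and 2 without the 2 farthest specimens. There the count was 3, since the astrocyte-like and oligodendrocyte-progenitor-like scores, at an r of 0.31 that did not pass, had -0.42 (adjusted p = 0.0489). Of the neighbour pairs 5 instead of 8 passed without the 2 farthest, and PIK3C2B with MDM4 turned from 0.53 to -0.30 (-0.29 without the 1 farthest). With an estimated correlation camera called 3 lists instead of 17 for pan-myeloid, and 0 instead of 7, 13 and 10 for proliferation, hypoxia and EGFR (1, 1 and 2 at an unadjusted p below 0.05), where fry called 10, 7 and 1. The estimated correlations ranged up to 0.94, since members of a list vary together. The counts of lists past the 95th percentile stayed within 1.5 times of 24 under the pseudocount and both scalings.

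Of the 80 genes named by r, 0 reversed under the alternatives run, which could be foreseen of genes chosen for the highest and lowest r in these specimens. Of these 80, 30 no longer passed with the mitochondrial share, 28 without the 6 specimens, 16 with the neuron and oligodendrocyte scores, 7 with the number of genes at 1 RPKM, 7 without the 2 most alike and 5 without the 2 farthest specimens. All 80 passed with Spearman ranks, no filter, the pseudocount of 0.1 and both scalings, and 38 were left to test, and passed, under the stricter filter. Depth limits low genes: 11.3 percent of genes were at 0 in the median specimen.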

Other observations

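Collagen and other matrix genes varied over a wide range. COL1A1 had a median of 5.77 RPKM and a maximum of 800 RPKM, COL3A1 10.4 and 1216 RPKM, and the proteoglycan gene LUM 2.06 and 518 RPKM, and each exceeded 4 times its median in 9 or 10 specimens. Of the pericyte and fibroblast list, 7 of 12 genes rose with the pan-myeloid score (COL1A2 0.67; RGS5, at 0.09, did not pass; camera adjusted p = 0.000367; adjusted p = 0.256 with an estimated correlation). Among neutrophil genes, S100A9 and S100A8, which form calprotectin, had medians of 46.5 and 19.6 RPKM and ranged up to 469 and 246 RPKM. Together with IL8 and the acute phase gene SAA1 they stood at one end of principal component 2, and TNR, BCAN and OLIG2 at the other.

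Genes of the receptor tyrosine kinase and ligand list did not vary together, but single members followed the pan-myeloid score. MERTK, a receptor for the uptake of dying cells, had an r of 0.82 with it by limma and a median of 7.31 RPKM, AREG an r of 0.63 and HGF 0.52, while 13 of 16 members did not pass, among them AXL (0.46) and MET (0.22). Of the interferon response list 5 of 16 rose with the pan-myeloid score, among them IFI44, IRF7, OAS2 and OAS1 (0.64, 0.62, 0.60 and 0.51; camera adjusted p = 0.00125; adjusted p = 0.386 with an estimated correlation). With the hypoxia score IFIT1 fell by limma (r = -0.65), alone of the 16, and the list was lower by camera (adjusted p = 0.00754; adjusted p = 0.737 with an estimated correlation). The cell cycle inhibitor gene CDKN1A rose with both hypoxia (0.61) and proliferation (0.64).

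Tests chosen after the results were seen were the random orders of the specimens, the scaling and the covariate tests of EGFR, and the scaling tests of proliferation. The mitochondrial share as a covariate and leaving out the 2 most alike specimens were also chosen after seeing the data, and the tests of the EGFR neighbours, of the macrophage and microglia lists given that share, of RNA quality and of chromosomes 7 and 10 use one of them. The bounds on intervals (95 percent, from 10000 resamples of specimens) were also set after a first look at the values. The labels give 1 group, so no biological explanation from the design was tested.

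Random orders of the specimens gave fewer genes than the real order for all 4 terms. The pan-myeloid, proliferation and hypoxia scores are means of genes from these same data that vary together. For these scores, lower counts under random orders could be foreseen, so they say little about the cause. Of 101 orders of each term, the real one included, 1 gave as many genes. The real counts were 2101 for pan-myeloid, 4105 for proliferation, 2206 for hypoxia and 1502 for EGFR, and the highest of the other orders 12, 383, 1612 and 1065. The random orders that called 1612 and 1065 genes point to a structure of the specimens that many genes share, which limits what the hypoxia and EGFR counts say about those terms.

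For the many genes related to EGFR, the RPKM scale set by mitochondrial reads stays open as a cause: 924 of the 1502 calls still passed after upper-quartile scaling and 715 after quantile normalization. At an unadjusted p below 0.05 by limma, 1498 and 1393 of them kept their direction in these 2 settings. With the mitochondrial share as a covariate 0 still passed. That covariate also takes out whatever else varies with the share, so the 0 cannot single out the scale. Brain-rich specimens with little tumour RNA stay open as well. With the neuron and oligodendrocyte scores as covariates 13 of the calls still passed, while the median slope of all 1502 went from 0.106 (median SE 0.0288) to 0.0747 (median SE 0.0309), which is 0.703 of its size (0.439 to 0.876), and 1109 of them had an unadjusted p below 0.05, so the calls ended with smaller slopes and slightly larger errors. Genes simulated at 1 assumed strength to follow only these 2 scores, and chosen by an absolute r of at least 0.5 with EGFR, kept 0.666 of their slope, so the share kept decides neither way. Copies of the EGFR region remain open for its neighbours: the median partial r of SEC61G, LANCL2 and VOPP1 with EGFR, given the mitochondrial share and both scores, was 0.535 (0.278 to 0.742).

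The macrophage list, but not the microglia list, was related to the mesenchymal-like list. Of the macrophage list, VCAN, TGFBI, THBS1 and S100A4, which tumour or stromal cells also express, are argued against as the cause. Without these genes the r was 0.814 (0.741 to 0.886). The mesenchymal-like list kept all its genes, of which 16 of 18 rose with the pan-myeloid score. Myeloid expression of those genes was not tested and stays open as a cause. Brain-rich specimens with little tumour RNA stay open: given the mitochondrial share and the neuron and oligodendrocyte scores, the difference between the 2 partial r was 0.560 (0.190 to 1.0; swap permutation p = 0.00183).

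Mitochondrial-encoded genes were lower where proliferation was higher (r of the 2 lists -0.793). The amount of neuron and oligodendrocyte RNA, as far as their scores measure it, is argued against as the whole cause. Given both scores the partial r was -0.754 (-0.873 to -0.563). Other brain cells, such as astrocytes, were not covered by these scores. The RPKM scale stays open as part of the cause, with an r of -0.795 (-0.893 to -0.625) after upper-quartile scaling and -0.678 (-0.838 to -0.446) after quantile normalization. Poor RNA quality stays open too: the r of the mitochondrial share with the number of genes at 1 RPKM was -0.463 over all specimens and -0.228 (-0.508 to 0.179) without the 2 most alike. Those 2 had the highest mitochondrial shares, so their removal also narrowed the range of the share.

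A hypothesis from knowledge of glioblastoma was that joint gain of chromosome 7 and loss of chromosome 10 may set the mean levels of their genes against each other. Over 12876 genes with a chromosome, the means of the 2 chromosomes had an r of -0.466, the rank 9 from the lowest among 231 pairs of chromosomes. Given the mitochondrial share and the neuron and oligodendrocyte scores the partial r was -0.312 (-0.645 to 0.225; p = 0.0821), at rank 35. The test did not place the pair among the lowest 5 percent, and with so wide an interval the hypothesis stays open.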
